A study of Mus musculus with 16 samples.

How the data were processed

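Total RNA from mouse embryo heads, as the sample titles name them, was measured at 3 embryonic stages, E9.5 (6 arrays), E11.5 (4 arrays) and E13.5 (6 arrays). The series title speaks of the brain and the source labels only of embryonic tissue, and how much tissue around the brain was taken is not given in the sources used here. The submitters describe the arrays of each stage as biological replicates. Per the labels, RNA was extracted with a lipid tissue spin column kit and labelled with biotin for 1-colour short oligonucleotide arrays. The E9.5 and E11.5 samples were labelled with a one-cycle in vitro transcription kit, and the E13.5 samples with an amplification kit of another maker. In every comparison with E13.5, stage and labelling kit therefore cannot be told apart.

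The deposited values are probe set intensity values on a linear scale, which the authors made with RMA, per the submitters' processing notes, and which are whole numbers in the table. RMA corrects the background, normalizes the arrays to one another and summarises the probes of a probe set. Its version, chip description and settings are not given in the sources used here. The quartiles of the 45101 probe set values were almost equal on all arrays, with medians of 32 on each array. Such values show changes relative to the other transcripts on an array and carry no information on the amount of RNA per embryo. Rounding to whole numbers makes coarse steps at the dim end, where the lowest values were 4 or 5. No read depth exists for arrays, so their number limits the precision.

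The log2 of each value was taken. After leaving out 64 control probe sets, 34945 probe sets named exactly 1 gene in the platform annotation, 932 named several genes and were not used, and 9160 were not named in the table used here. Symbols were looked up through gene identifiers in a RefSeq table of assembly GRCm38.p6, which changed 0 symbols; 204 probe sets kept the platform symbol because their identifier was not matched. Each gene was represented by the probe set with the highest mean over the 16 arrays, giving 18194 genes, of which 9009 had 2 or more probe sets. Where called probe sets of a named gene disagreed in sign, this is stated with the gene. No column of sample values was left unused (0 columns), and 0 pairs of arrays held identical columns.

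Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with all 16 arrays in 1 model and Benjamini-Hochberg adjustment over genes within each comparison. Genes with an adjusted p under 0.05 were called, and a second count took called genes that differed at least 2-fold (1 on the log2 scale). A moderated F test compared the 3 stages together. Gene errors are standard errors of the log2 difference, and stage levels are means ± SD of log2 intensity.

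A set of 38 gene lists, with at least 5 measured members each, was tested with limma's camera at a preset correlation of 0.01, adjusted over all lists and comparisons together. Camera asks whether a list moved relative to the other genes. The test was repeated with an estimated correlation, and fry was run as an alternative, which tests whether a list's genes move one way on balance without comparing them with other genes. Lists that kept their call with an estimated correlation had camera adjusted p of 0.00249 to 0.0486 in that test. For most of them the text gives the value at the preset correlation alone. Of 1072 genes in the lists, 923 were measured. Levels of control probe sets were compared with two-sided exact permutation tests, whose smallest possible p was 0.00476 for 4 against 6 arrays and 0.00216 for 6 against 6. These tests treated the arrays of a stage as independent.

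The comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule took, per comparison, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose arrays did not overlap, skipping gene models without a name of their own. For each list discussed it took up to 4 called members with the largest change and up to 2 called members with the largest change against the list's median. The text names the 8 and 8 in full and a part of the list members so taken, and that part was chosen after their values were seen. The alternatives were quantile normalization, median centring, 3 other treatments of probe sets, a filter on the dimmest 25% of genes, fits of only the stages compared, a trended and robust variance, array weights, a covariate for Y-linked genes, a random block for the title prefix of the E13.5 samples, and leaving out each array in turn. The second-brightest probe set of each gene, and leaving out the E9.5 samples 13 and 15 together, were added after the data were seen. The tests of the 3 patterns weighed at the close were also set up after the data were seen, and those of a lower neural share and of a smaller progenitor share were changed after their values were seen, the former more than once.

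The programs were tested on simulated data for the 18194 genes. In each comparison, 66 or 67 genes were changed at each size, with noise independent between genes and arrays. In E11.5 versus E9.5, 67.2% of simulated changes of 0.5 log2 units were called, and 100% of changes of 1 and of 2 log2 units; 6.32% of the calls were false. In E13.5 versus E11.5, the shares were 65.7% for changes of 0.5 and 100% for 1 and 2, with 4.84% false calls. In E13.5 versus E9.5, they were 85.1% for changes of 0.5 and 100% for 1 and 2, with 8.21% false calls. The real data differ: 54.9% to 61.8% of genes were called, and E13.5 arrays of 1 title prefix had a consensus correlation of 0.60. These shares therefore need not hold for the real comparisons.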

Results

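Transcript levels in mouse embryo heads were measured on 16 arrays at E9.5 (n = 6), E11.5 (n = 4) and E13.5 (n = 6), for a study of early brain development. The question each comparison addressed was which transcripts changed between the stages. The sample titles name the head and the series title the brain, and how much tissue around the brain was taken is not known. Markers of facial mesenchyme, muscle, vessels, blood, surface ectoderm and eye were therefore counted beside the neural genes, and their values depend on that extent. Of 18194 genes, 13798 (75.8%) differed between stages by the moderated F test.

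The arrays grouped by stage. The first principal component held 65.3% of the variance and ordered the stages by age, and the second held 21.2% and set E11.5 apart from both other stages. Correlations across genes lay between 0.988 and 0.996 within E9.5, between 0.989 and 0.993 within E11.5 and between 0.996 and 0.998 within E13.5, against 0.923 to 0.938 between E9.5 and E13.5. The E9.5 samples 13 and 15 stood apart from the other arrays on the third component (3.17% of the variance), with scores of 26.0 and 22.5. Signal from the Y-linked gene Kdm5d was present on 3 of 6, 2 of 4 and 3 of 6 arrays, so each stage held equal numbers of arrays with and without it.

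**Figure D1:**
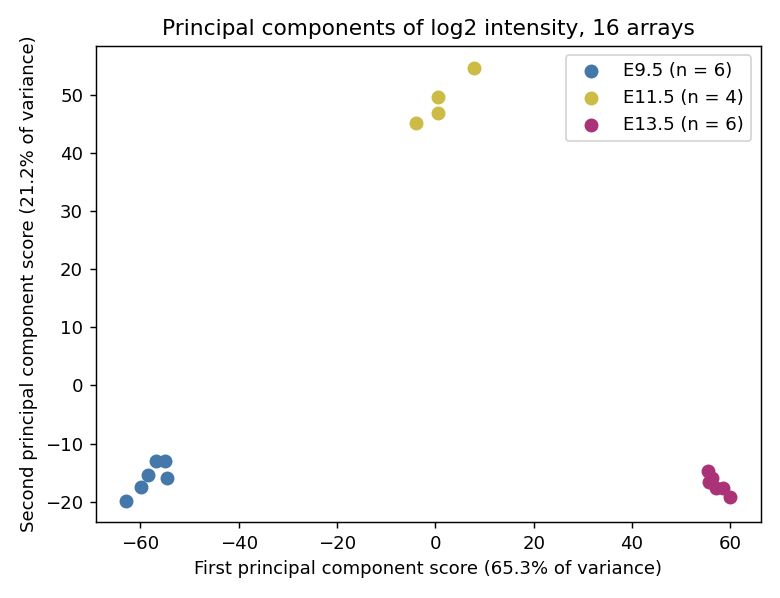
Principal component scores of the 16 arrays from log2 intensities of 18194 genes. Each point is an array, coloured by stage; the horizontal axis (65.3% of variance) orders the stages by age and the vertical axis (21.2%) places the 4 E11.5 arrays above all others.

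Control probe sets also differed between stages. The poly-A spike-ins, transcripts added to the RNA, had a mean log2 intensity of 8.31 ± 0.24 (SD, n = 6) at E9.5 and 5.71 ± 0.19 (n = 4) at E11.5, a difference of -2.60 (exact permutation p = 0.00476). At E13.5 they were at 5.44 ± 0.11 (n = 6). Each pairwise difference between stages of the spike-ins, the hybridisation controls and 18S ribosomal RNA had an adjusted p of at most 0.033 by the exact tests, over 30 such tests of controls. The E9.5 and E11.5 samples were labelled with the same kit, yet these controls differed between them. A difference in handling that went with stage therefore cannot be told apart from stage in E11.5 versus E9.5 either. Hybridisation controls were at 10.66 ± 0.51, 11.60 ± 0.23 and 10.25 ± 0.07, and 18S ribosomal RNA was at 7.25 ± 0.42, 10.19 ± 0.30 and 10.74 ± 0.16, in stage order. The 3′ to 5′ difference of the Gapdh control probe sets, a sign of RNA integrity, was 0.18 ± 0.10 at E9.5 and 0.14 ± 0.05 at E11.5 (difference -0.038, exact permutation p = 0.667) and 0.04 ± 0.03 at E13.5, lower than at E11.5 by an exact permutation test (p = 0.00476, adjusted p = 0.00714). That of beta-actin was 0.82 ± 0.16, 0.56 ± 0.05 and 0.47 ± 0.03, and it differed by -0.25 between E9.5 and E11.5 (exact permutation p = 0.0286, adjusted p = 0.033) and by -0.089 between E11.5 and E13.5 (exact permutation p = 0.019, adjusted p = 0.0238). That of the poly-A spike-ins was 1.01 ± 0.19, 1.76 ± 0.22 and 1.99 ± 0.17, a rise of 0.75 between E9.5 and E11.5 (exact permutation p = 0.00476, adjusted p = 0.00714) and a difference of 0.23 between E11.5 and E13.5 (exact permutation p = 0.105, adjusted p = 0.112).

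From E9.5 to E11.5, neuronal genes rose and genes of growth, proliferation and early embryonic state fell. Dcx, a microtubule-associated protein of migrating neurons, rose 25.3-fold, from a log2 intensity of 6.22 ± 1.23 (SD, n = 6) to 10.89 ± 0.03 (n = 4; log2 difference 4.66 ± 0.40 SE, adjusted p = 5.7e-09). Dcx was at 4.81 and 4.75 in the E9.5 samples 13 and 15, which stood apart on the third component, and between 6.04 and 7.60 in the other E9.5 samples; without both samples its log2 difference was 3.94. Lin28a, an RNA-binding protein of early embryonic cells, fell 43.3-fold, from 10.73 ± 0.15 to 5.29 ± 0.35 (log2 difference -5.44 ± 0.13, adjusted p = 9.9e-17). Genes of ribosome assembly fell by a median of 1.23 log2 units. In all, 5633 genes were higher and 4887 lower at E11.5, of which 1106 and 872 differed at least 2-fold. The 1106 became 603 with the mean of all probe sets of a gene and 715 with the second-brightest. The arrays of the 2 stages did not overlap for 6858 genes, where chance gives 0.952% of genes.

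Among the 8 largest rises were also the transcription factors Nhlh2 (log2 difference 4.27 ± 0.35, 19.3-fold, adjusted p = 2.6e-09) and Bcl11b (log2 difference 4.23 ± 0.14, 18.8-fold, adjusted p = 1.3e-14), the thyroid hormone carrier Ttr (log2 difference 4.22 ± 0.23, 18.6-fold, adjusted p = 9.2e-12) and the Notch-related receptor Dner (log2 difference 3.98 ± 0.18, 15.8-fold, adjusted p = 5.7e-13). Nhlh2 was at 3.91 and 4.17 in the E9.5 samples 13 and 15, under the other E9.5 samples (5.09 to 6.27), and its log2 difference without both was 3.65. The other 3 were Depp1 (log2 difference 5.57 ± 0.21, 47.7-fold, adjusted p = 1.1e-13), Pik3cd (log2 difference 4.89 ± 0.20, 29.7-fold, adjusted p = 1.5e-13) and Sema3f (log2 difference 4.26 ± 0.14, 19.1-fold, adjusted p = 2.3e-14). Their other probe sets moved little, with median log2 differences of 0.33 (not called), 0.16 and 0.41. The largest falls after Lin28a were those of Car4, a carbonic anhydrase (log2 difference -4.43 ± 0.17, 21.6-fold, adjusted p = 9.1e-14), and the orphan nuclear receptor Nr6a1 (log2 difference -3.43 ± 0.15, 10.8-fold, adjusted p = 6.7e-13), 2 of whose 4 other probe sets also fell and 1 rose. Prtg (-3.38 ± 0.11, adjusted p = 1.2e-14), Irs4 (-3.33 ± 0.18, adjusted p = 5.7e-12), Trim71 (-2.99 ± 0.12, adjusted p = 1.3e-13), the retinoic acid enzyme gene Aldh1a3 (-2.93 ± 0.15, adjusted p = 5.7e-12) and the phosphatase gene Dusp9 (-2.82 ± 0.16, adjusted p = 1.3e-11) completed the 8. The other probe set of Irs4 fell less, by a called difference of -0.49.

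Neuronal lists rose together. Of the pan-neuronal cytoskeleton and RNA-binding genes, 24 of 25 measured members rose, 0 fell and 1 was not called, or 24 and 0 adjusted over the list alone (median log2 difference 2.31, camera adjusted p = 4.4e-14; adjusted p = 0.0535 with an estimated correlation). Stmn2 (3.21 ± 0.21) and Map2 (3.15 ± 0.18), both microtubule regulators, rose with Dcx. The E9.5 samples 13 and 15 were lowest of the stage for both genes, with Stmn2 at 6.34 and 6.27 and Map2 at 5.86 and 6.41. Among proneural and early neuronal transcription factors, 21 of 24 measured members rose, 0 fell and 3 were not called, or 21 and 0 adjusted over the list alone (median 1.21, adjusted p = 2.5e-09). Among GABAergic lineage genes, 15 of 16 measured members rose, 0 fell and 1 was not called, or 15 and 0 adjusted over the list alone (median 1.21, adjusted p = 1.0e-07), with Gad1, which makes GABA, up by 3.22 ± 0.12. Among synaptic and neurotransmitter release genes, 21 of 23 measured members rose, 0 fell and 2 were not called, or 21 and 0 adjusted over the list alone (median 1.09, adjusted p = 5.0e-09), and among axon guidance and growth cone genes 19 of 28 measured members rose, 4 fell and 5 were not called, or 20 and 4 adjusted over the list alone (median 0.65, adjusted p = 3.5e-05). The glutamate, acetylcholine and monoamine list was not called (8 members rose and 2 fell, adjusted p = 0.138), although the vesicular glutamate transporter gene Slc17a6 rose by 3.41 ± 0.17. It was called with the mean of all probe sets of a gene (adjusted p = 0.0266) and with the second-brightest probe set (0.0154). Gad1 and Slc17a6 had mean intensities at E9.5 under 12, the lower quartile of each array, near background, so the sizes of their rises are read as lower limits.

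Glial lineage genes rose too: 13 of 19 measured members rose, 0 fell and 6 were not called, or 13 and 0 adjusted over the list alone (median 1.25, adjusted p = 3.7e-05), led by the matrix proteoglycan Ncan (3.46 ± 0.09) and the transcription factor Nfia (3.23 ± 0.17). Of the neuroepithelial and radial progenitor genes, 14 of 20 measured members rose, 3 fell and 3 were not called, or 15 and 3 adjusted over the list alone (median 0.63, adjusted p = 0.00105; adjusted p = 0.236 with an estimated correlation). Id4 (3.01 ± 0.22), at 8.13 and 8.47 in the E9.5 samples 13 and 15 and at 8.72 or more in the others, and the Notch target Hes5 (1.64 ± 0.11) rose. Among cell cycle exit genes, 12 of 15 measured members rose, 1 fell and 2 were not called, or 13 and 1 adjusted over the list alone (median 0.98, adjusted p = 1.8e-05), with the cyclin-dependent kinase inhibitor Cdkn2c up by 2.40 ± 0.10. The camera adjusted p of the cell cycle exit list was 0.0476 with an estimated correlation.

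Genes of growth fell as groups. Among ribosome biogenesis genes, 1 of 36 measured members rose, 34 fell and 1 was not called, or 1 and 35 adjusted over the list alone (adjusted p = 1.6e-17). The nucleolar genes Nolc1 (-2.40 ± 0.11) and Rrp12 (-2.17 ± 0.14) were the examples with the largest falls, whereas Nop10 rose (0.99 ± 0.10), its other probe set not being called (1 member rose in all). Among DNA replication genes, 3 of 37 measured members rose, 32 fell and 2 were not called, or 3 and 32 adjusted over the list alone (median -0.64, adjusted p = 6.0e-09). The helicase subunit gene Mcm5 fell (-1.34 ± 0.08), and Fen1 rose by 1.82 ± 0.13 on its brightest probe set while its other probe set fell, by a called difference of -0.85. Among mitotic cell cycle genes, 3 of 34 measured members rose, 23 fell and 8 were not called, or 3 and 24 adjusted over the list alone (median -0.43, adjusted p = 2.1e-06). With an estimated correlation, the camera adjusted p was 0.0127 for ribosome biogenesis, 0.0323 for DNA replication and 0.0409 for mitotic genes. The poly-A spike-ins fell over the same interval by 2.60 log2 units.

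Among glycolysis genes, 3 of 20 measured members rose, 15 fell and 2 were not called, or 3 and 15 adjusted over the list alone (median -0.78, adjusted p = 1.3e-05; adjusted p = 0.0904 with an estimated correlation), and the glucose transporter gene Slc2a3 was at -2.54 ± 0.10. Of the chaperones, 24 fell and 0 rose (adjusted p = 3.2e-08), with mitochondrial Hspa9 at -1.69 ± 0.09 and 2 of its 4 other probe sets also falling and 1 rising. Translation factors (18 fell, 4 rose, adjusted p = 1.6e-04), proteasome subunits (22 and 4, adjusted p = 2.0e-06), tricarboxylic acid cycle genes (16 and 1, adjusted p = 8.0e-05) and cytosolic ribosomal proteins (23 and 6, adjusted p = 0.00189) also fell as lists. The pluripotency-associated list fell (8 members fell and 1 rose, camera adjusted p = 3.2e-04, and 0.0486 with an estimated correlation). Brain regional patterning genes fell (15 fell, 6 rose, adjusted p = 0.0184; adjusted p = 0.0646 with an estimated correlation), among them the eye and forebrain factor Six6 (-2.02 ± 0.17) and the midbrain-hindbrain factor En1 (-1.68 ± 0.10).

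Markers of other tissues changed in the same interval. Connective tissue genes rose (18 of 19, median 1.23, adjusted p = 3.6e-09), with the collagen genes Col1a1 up by 3.61 ± 0.15 and Col6a3 by 2.58 ± 0.14. Macrophage and microglia genes rose (18 of 22, median 1.03, adjusted p = 3.9e-08), including the growth factor receptor Csf1r (2.92 ± 0.16) and F13a1 (2.65 ± 0.10). Laptm5, of the same list, rose by 3.94 ± 0.22 on its brightest probe set, against a median of 0.095 over 4 others. Neural crest and branchial mesenchyme genes rose (13 of 22, adjusted p = 0.00101; adjusted p = 0.0535 with an estimated correlation). Surface ectoderm genes fell (11 of 22 fell and 3 rose, camera adjusted p = 0.0183, and 0.311 with an estimated correlation). The keratins Krt18 and Krt8 were at -2.46 ± 0.13 and -1.79 ± 0.19. The E9.5 samples 13 and 15 were highest of the stage for both, with Krt18 at 8.58 and 8.72 and Krt8 at 9.36 and 9.13.

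The hypoxia list was at the threshold (median -0.21, adjusted p = 0.0463; adjusted p = 0.0904 with an estimated correlation). It lost its call without E9.5 sample 16 or 19 or E11.5 sample 52 (adjusted p up to 0.0651), without the dimmest genes, and with the mean of all probe sets or the second-brightest (up to 0.270). The latter pair of settings also ended the calls of the patterning list (adjusted p up to 0.0998) and the surface ectoderm list (up to 0.0733). Lists not called were immediate early and stress genes (adjusted p = 0.155, with Myc at -2.10 ± 0.12), endothelial and pericyte genes (0.275), cartilage and bone (0.636), skeletal muscle (0.722), globin and erythroid genes (0.519), lens and pigment genes (0.443) and choroid plexus genes (0.139). With the second-brightest probe set, the lens and pigment list (adjusted p = 0.0215) and the choroid plexus list (0.0451) were called. The HOX (0.951), cholesterol synthesis (0.411), imprinted growth (0.426), replication-dependent histone (0.756), spliceosome (0.697) and oxidative phosphorylation lists (0.917) were not called either. For skeletal muscle the median was above 0 and the mean and test below, and for oxidative phosphorylation the median was below 0 and the mean and test above.

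**Figure D2:**
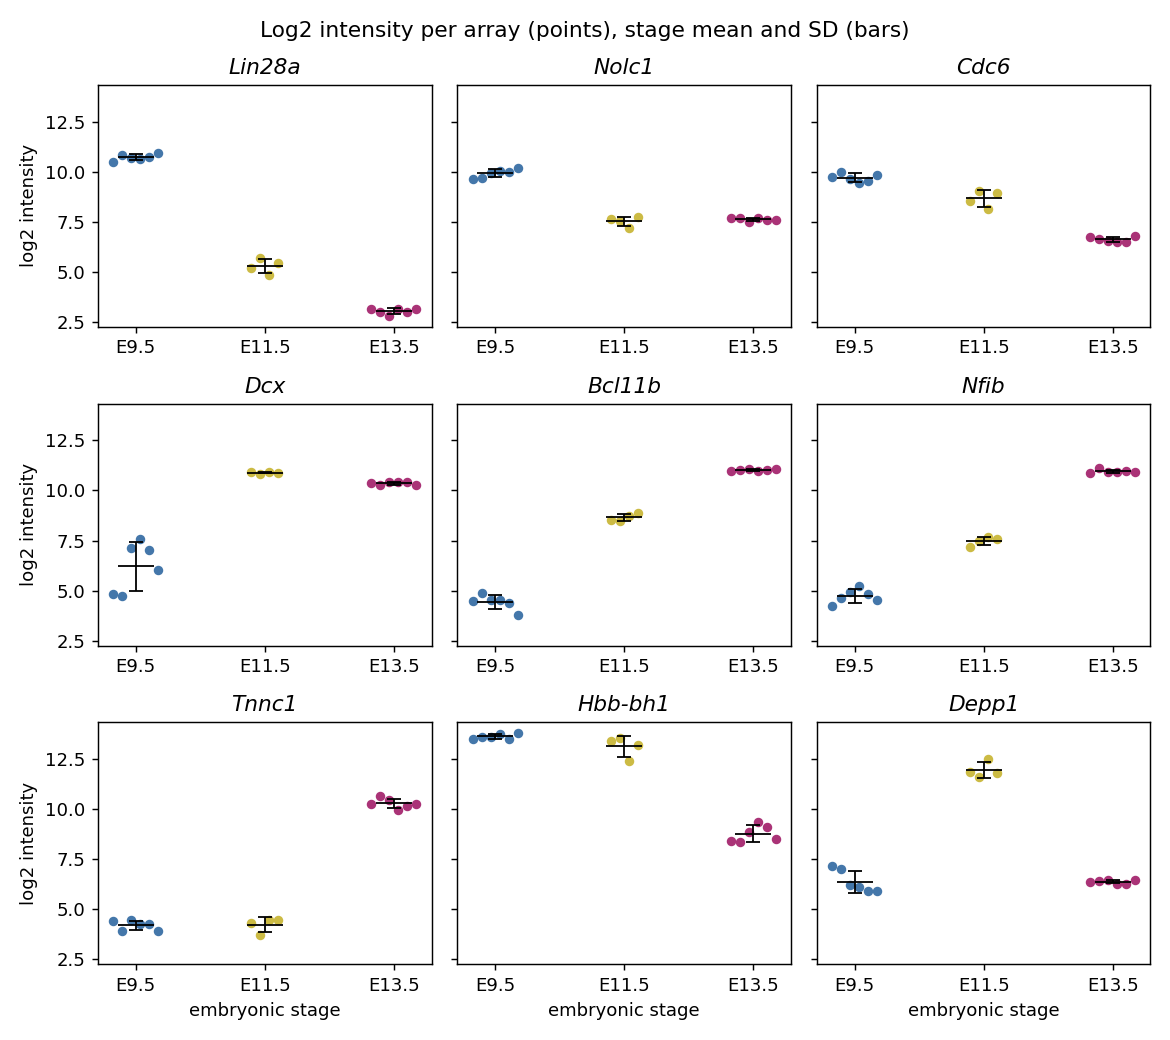
Log2 intensity of 9 named genes on each array (points) at E9.5 (n = 6), E11.5 (n = 4) and E13.5 (n = 6), with the stage mean and SD as bars. Lin28a fell from 10.73 ± 0.15 to 3.05 ± 0.15, Tnnc1 rose between E11.5 and E13.5, and the Depp1 probe set was high on the 4 E11.5 arrays and near 6.38 at both other stages.

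From E11.5 to E13.5, genes of muscle, cartilage and connective tissue rose most, pan-neuronal and synaptic genes went on rising, and mitotic cell cycle genes and globin and erythroid genes fell. With an estimated correlation, the pan-neuronal list (adjusted p = 0.276) and the globin and erythroid list (adjusted p = 0.126) were no longer called. Tnnc1, a troponin of slow muscle and heart, rose 66.3-fold, from a log2 intensity of 4.24 ± 0.36 (SD, n = 4) to 10.29 ± 0.25 (n = 6; log2 difference 6.05 ± 0.16 SE, adjusted p = 1.2e-16). The embryonic globin gene Hbb-bh1 fell 20.4-fold, from 13.13 ± 0.52 to 8.78 ± 0.41 (log2 difference -4.35 ± 0.20, adjusted p = 5.3e-13). In all, 5075 genes were higher and 4906 lower at E13.5, of which 1052 and 692 differed at least 2-fold (692 and 438 with the mean of all probe sets of a gene), and arrays did not overlap for 7819 genes (chance 0.952%). The E13.5 arrays alone were labelled with another kit, so stage and kit cannot be told apart in this comparison or in that of E13.5 with E9.5.

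The 8 largest rises were muscle, cartilage and connective tissue genes. After Tnnc1 came the myosin light chain Myl1 (5.76 ± 0.16, adjusted p = 2.9e-16), the actins Actc1 (log2 difference 5.66 ± 0.10, 50.5-fold, adjusted p = 5.5e-19) and Acta1 (5.02 ± 0.18, adjusted p = 1.1e-14), the cartilage gene Cnmd (log2 difference 5.44 ± 0.13, 43.5-fold, adjusted p = 6.3e-17) and the proteoglycan Dcn (5.11 ± 0.15, adjusted p = 5.1e-16), whose other probe set differed by 0.45. Tnnt1 (4.96 ± 0.17, adjusted p = 6.1e-15) and embryonic myosin Myh3 (4.80 ± 0.15, adjusted p = 1.9e-15) were the others. The E13.5 titles carry the prefix B62 or B63. Arrays of 1 prefix had a consensus correlation of 0.60, but these errors and p-values treat them as independent. Cnmd was at 9.40 to 9.57 in B62 and at 9.04 to 9.12 in B63. Myl1, Acta1 and Dcn were also higher in every B62 sample, while Tnnc1, Actc1, Tnnt1 and Myh3 overlapped. The E11.5 level of Myl1 was under the lower quartile of 12, so the size and rank of its rise rest on a level near background. Cnmd and Myh3, at mean E11.5 intensities of 14.2 and 16.1, lay little above that quartile. Of the skeletal muscle list, 19 of 22 measured members rose, 0 fell and 3 were not called, or 19 and 0 adjusted over the list alone (median 3.74, adjusted p = 1.5e-14). Of the cartilage and bone list, 15 of 18 measured members rose, 0 fell and 3 were not called, or 15 and 0 adjusted over the list alone (median 1.66, adjusted p = 2.4e-09), and of the connective tissue list 17 of 19 measured members rose, 0 fell and 2 were not called, or 17 and 0 adjusted over the list alone (median 1.68, adjusted p = 1.5e-11). With an estimated correlation, the camera adjusted p was 0.0118 for skeletal muscle, 0.0127 for cartilage and bone and 0.00834 for connective tissue. Hybridisation controls fell over this interval by 1.35 log2 units.

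The largest falls were of different kinds. The erythroid genes Hemgn (-5.19 ± 0.27, adjusted p = 4.1e-12) and Hbb-bh1 fell to levels below those of both earlier stages. The E13.5 level of Hemgn was under the lower quartile of 12, and the size of its fall is read as a lower limit. Depp1 (-5.58 ± 0.21, adjusted p = 3.3e-14), Pik3cd (-4.10 ± 0.20, adjusted p = 9.4e-13), Sema3f (-3.64 ± 0.14, adjusted p = 4.9e-14), Nrip2 (-3.88 ± 0.16, adjusted p = 1.5e-13) and Kalrn (-3.71 ± 0.14, adjusted p = 1.8e-14) were high at E11.5 alone on their brightest probe set. The other probe set of Depp1 rose by 0.44, 3 of 7 others of Kalrn rose and 2 fell, and the medians of the others were -0.12 for Pik3cd, -0.11 for Sema3f and -0.17 for Nrip2. Mid1, a microtubule-associated ubiquitin ligase, fell by 3.80 ± 0.32 (adjusted p = 4.1e-09), against a median of -0.31 over its 2 other probe sets.

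Pan-neuronal, synaptic and axon guidance lists rose further, and the glutamate, acetylcholine and monoamine list rose in this interval. Pan-neuronal genes had 17 members that rose and 2 that fell (median 0.92, adjusted p = 8.8e-05; adjusted p = 0.276 with an estimated correlation), with Gap43 of growth cones up by 2.32 ± 0.10 and the splicing regulator Celf4 by 2.51 ± 0.09. Synaptic genes rose (17 rose, 1 fell, median 0.75, adjusted p = 1.6e-05). Snap25, a synaptic vesicle fusion protein, rose by 2.09 ± 0.24 on its brightest probe set, and its other probe set fell (-0.39). The glutamate, acetylcholine and monoamine list rose (10 rose, 2 fell, adjusted p = 0.0151; not called without the dimmest genes or with the second-brightest probe set, at up to 0.176), with the glutamate receptor gene Gria2 at 3.23 ± 0.18, whose second-brightest probe set was not called. Axon guidance genes rose (15 and 5, adjusted p = 0.00167; adjusted p = 0.0538 with an estimated correlation). GABAergic genes were not called as a list (10 rose, 3 fell, adjusted p = 0.0731). Among proneural factors 6 rose and 12 fell (adjusted p = 0.25), with Neurod6 of cortical neurons up by 4.41 ± 0.08 and Neurod4 at -2.62 ± 0.19. Neurod6 was under the lower quartile of 12 at E11.5, as was Hoxb5 of the HOX list, so the sizes of both rises are read as lower limits.

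Cell cycle genes fell. Of the mitotic list, 3 of 34 measured members rose, 28 fell and 3 were not called, or 3 and 28 adjusted over the list alone (median -0.65, adjusted p = 3.5e-08), with the cytokinesis gene Ect2 at -1.93 ± 0.10. Of the DNA replication list, 5 of 37 measured members rose, 24 fell and 8 were not called, or 6 and 24 adjusted over the list alone (median -0.52, adjusted p = 2.6e-06; adjusted p = 0.0599 with an estimated correlation), with the origin licensing gene Cdc6 at -2.05 ± 0.14. Progenitor genes were at the threshold (5 rose, 11 fell, adjusted p = 0.0463; adjusted p = 0.468 with an estimated correlation). That call was lost without E9.5 sample 13 or 16 or E11.5 sample 33, 36 or 52 (adjusted p up to 0.0584), without E9.5 samples 13 and 15 together, without the dimmest genes and with the second-brightest probe set (up to 0.0913). Hes5 fell by 2.21 ± 0.11, and Sox1 was at -1.79 ± 0.13, the other probe set of Sox1 not being called (-0.11). The cell cycle exit list was not called (adjusted p = 0.278), though the growth inhibitor Cdkn1c rose by 1.70 ± 0.13. Ribosome biogenesis genes, which were lower at E11.5 than at E9.5, split evenly (11 rose and 11 fell, adjusted p = 0.771, the median above 0 and the mean and test below).

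Regional and glial genes went different ways. Brain patterning genes fell (13 fell, 2 rose, adjusted p = 0.0197; adjusted p = 0.0669 with an estimated correlation), with the signal Shh at -2.85 ± 0.10, while Gbx2 of the anterior hindbrain rose by 1.58 ± 0.17. HOX genes rose (11 rose, 2 fell, adjusted p = 0.00118; adjusted p = 0.119 with an estimated correlation), with Hoxb5 up by 2.68 ± 0.14 and Hoxc4 by 1.90 ± 0.17. The glial list was not called (6 rose, 7 fell, adjusted p = 0.573), yet the nuclear factor I genes Nfix (3.96 ± 0.17) and Nfib (3.48 ± 0.14) rose. Pluripotency-associated genes fell further (9 fell, 2 rose, adjusted p = 0.00261; adjusted p = 0.0872 with an estimated correlation).

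Other tissue markers moved in the same interval. Globin and erythroid genes fell (13 fell, 1 rose, adjusted p = 2.1e-05; adjusted p = 0.126 with an estimated correlation), and the rising member was Hbb-b2 (0.66 ± 0.10), whose other probe set was not called. Lens and retinal pigment genes rose (12 of 21, median 1.07, adjusted p = 6.7e-06), the lens crystallin Cryba1 by 4.67 ± 0.14. Surface ectoderm genes rose (14 rose, 3 fell, adjusted p = 0.00196; adjusted p = 0.198 with an estimated correlation), with the keratins Krt15 up by 4.01 ± 0.11 and Krt14 by 3.44 ± 0.09. Endothelial genes rose (14 rose, 2 fell, adjusted p = 7.6e-04). Macrophage genes rose (14 and 3, adjusted p = 0.0178; adjusted p = 0.0851 with an estimated correlation), a call lost without probe sets marked as shared (0.0578), and the complement gene C1qa rose by 1.54 ± 0.11. Choroid plexus genes were at the threshold (7 and 4, adjusted p = 0.0459; adjusted p = 0.131 with an estimated correlation), lost without E9.5 sample 15 or 22, E11.5 sample 51 or E13.5 sample B63E6K (up to 0.0526) and without E9.5 samples 13 and 15 together (0.0531), with the water channel Aqp1 at 2.59 ± 0.09. The neural crest list was not called (adjusted p = 0.116).

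Metabolic and housekeeping lists went both ways. Oxidative phosphorylation subunits rose (43 rose, 9 fell, median 0.49, adjusted p = 1.5e-06; adjusted p = 0.0807 with an estimated correlation), with Ndufs8 up by 1.97 ± 0.12. Cytosolic ribosomal proteins rose (27 rose, 6 fell, adjusted p = 0.00107). Cholesterol synthesis (adjusted p = 0.0062; adjusted p = 0.347 with an estimated correlation) and spliceosome genes (adjusted p = 0.00261; adjusted p = 0.102 with an estimated correlation) fell, calls lost without probe sets marked as shared (0.125 and 0.0680) and, for cholesterol synthesis, with the second-brightest probe set (0.143). Proteasome subunits rose at the threshold (16 rose, 7 fell, adjusted p = 0.0463; adjusted p = 0.235 with an estimated correlation), lost without E9.5 sample 15, E11.5 sample 33 or 51 or E13.5 sample B62E8K or B63E6K (up to 0.0649), and with 7 other settings of scaling, probe sets, dim genes, array weights or samples (up to 0.0923). Not called were glycolysis (adjusted p = 0.254), hypoxia (0.19), tricarboxylic acid cycle (0.206), translation factor (0.978), chaperone (0.267), imprinted growth (0.278), histone (0.443) and immediate early lists (0.136). For translation factors the median and mean were above 0 and the test below. Aldoc, of the glycolysis and hypoxia lists, rose by 4.65 ± 0.15 on its brightest probe set and was not called on the other (-0.0085), and Klf4 of the immediate early list rose by 3.12 ± 0.12.

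**Figure D3:**
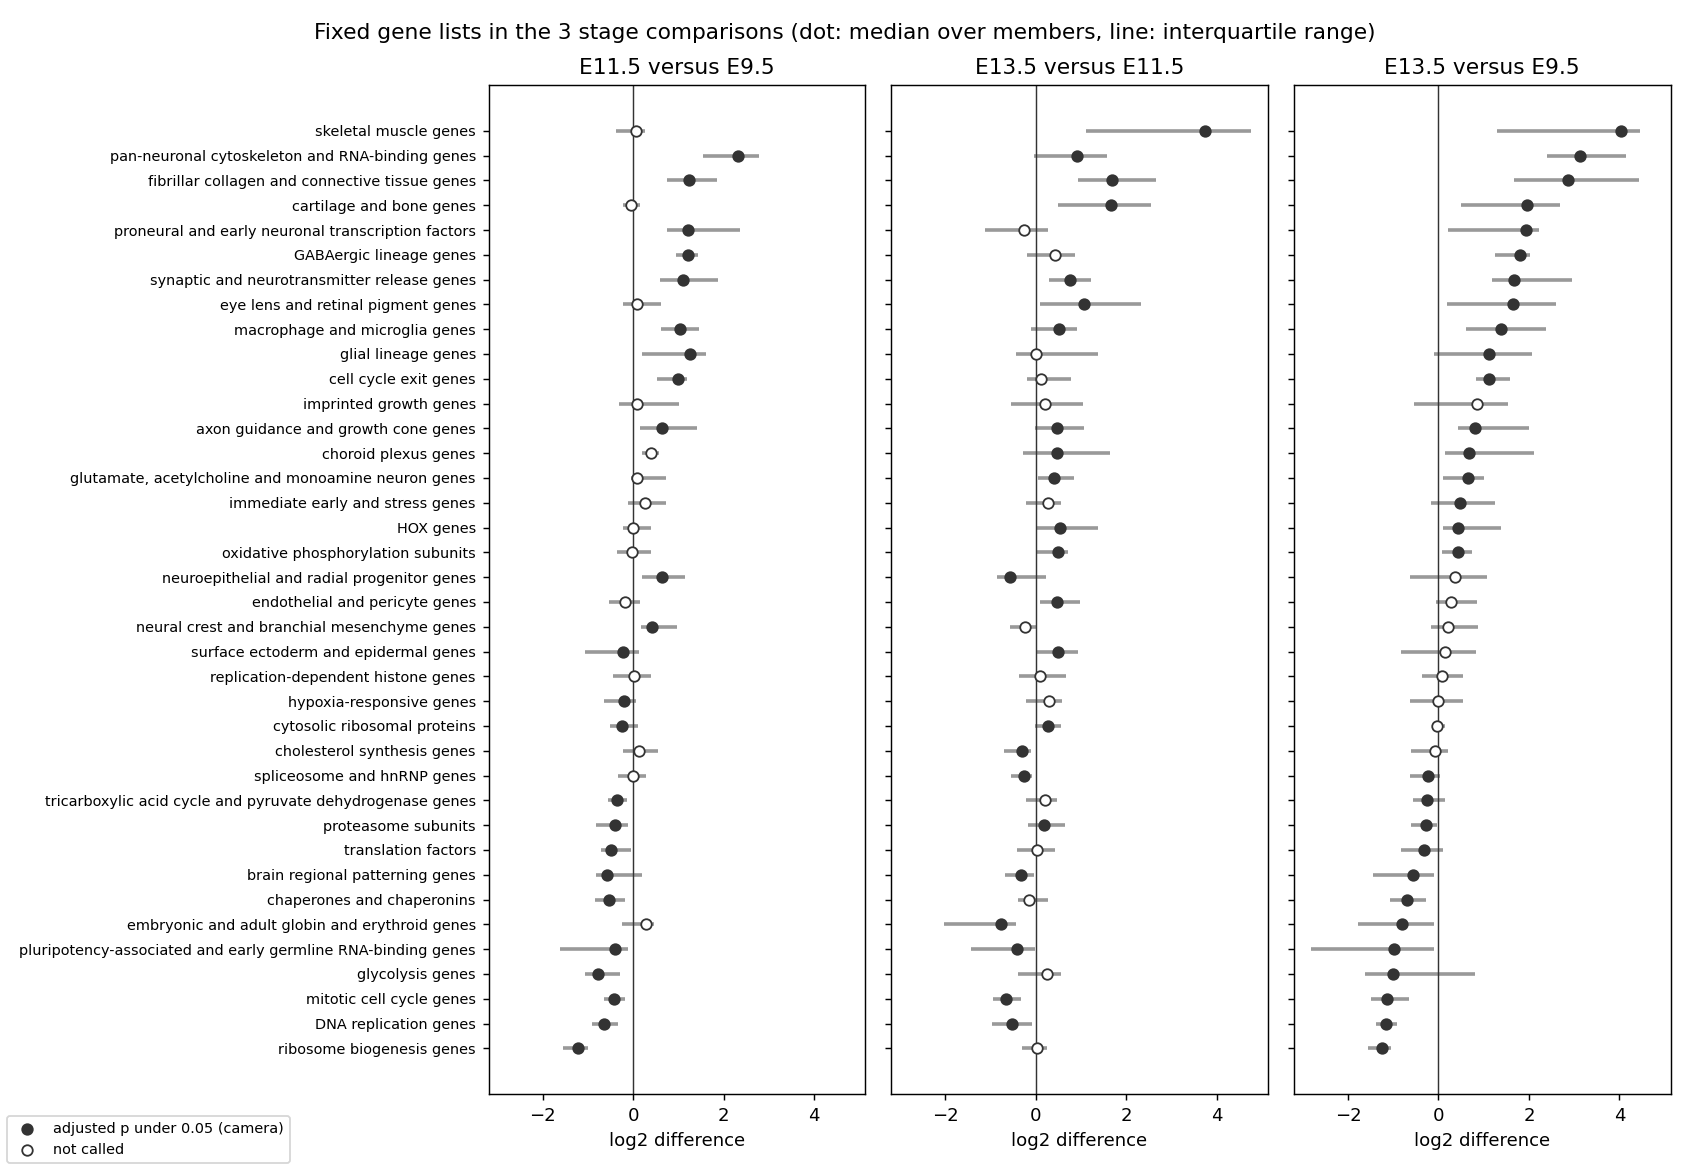
Median log2 difference (dots) and interquartile range (lines) of the 38 gene lists in the 3 comparisons; filled dots have an adjusted p under 0.05 with camera. Ribosome biogenesis genes lie at -1.23 and skeletal muscle genes at 0.06 in E11.5 versus E9.5, and at 0.04 and 3.74 in E13.5 versus E11.5.

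Over the whole interval from E9.5 to E13.5, differentiated neural, muscle and connective tissue genes were higher and early embryonic and cell cycle genes lower. Bcl11b rose 96.1-fold (log2 difference 6.59 ± 0.12 SE, adjusted p = 1.9e-19) and Lin28a fell (log2 difference -7.68 ± 0.11, adjusted p = 1.3e-20), with n = 6 at each stage. Here too, errors and p-values treat the E13.5 arrays as independent, though arrays of 1 title prefix had a consensus correlation of 0.60. In all, 5945 genes were higher and 5302 lower at E13.5, of which 1807 and 1288 differed at least 2-fold. Arrays did not overlap for 8143 genes, where chance gives 0.216%.

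The other largest rises were Ttr (log2 difference 6.62 ± 0.21, 98.1-fold, adjusted p = 2.6e-16), Dcn (6.34 ± 0.13, adjusted p = 8.5e-19, its other probe set at 0.65), Nfib (6.22 ± 0.12, adjusted p = 5.1e-19), Tnnc1 (6.09 ± 0.14, adjusted p = 3.7e-18), Col6a3 (5.95 ± 0.13, adjusted p = 1.0e-18), Ogn (5.78 ± 0.14, adjusted p = 7.5e-18) and Myl1 (5.63 ± 0.14, adjusted p = 1.1e-17). The other largest falls were Car4 (-5.13 ± 0.15, adjusted p = 9.9e-17), the transcription factor Sall4 (32-fold lower, adjusted p = 1.6e-17), Hbb-bh1 (-4.85 ± 0.18, adjusted p = 3.7e-15), Trim71 (-4.52 ± 0.11, adjusted p = 5.1e-18), Prtg (-4.45 ± 0.10, adjusted p = 1.5e-18), Nr6a1 (-4.30 ± 0.14, adjusted p = 4.0e-16) and Irs4 (-4.22 ± 0.16, adjusted p = 4.2e-15). The other probe set of Irs4 fell less, by -1.44. Lin28a and Car4 at E13.5, and Myl1, Ogn, Neurod6, Gad1 and Chl1 at E9.5, had mean intensities under the lower quartile of 12, so the sizes of their differences are read as lower limits and their ranks as approximate.

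Among synaptic genes 23 of 23 measured members rose, 0 fell and 0 were not called, or 23 and 0 adjusted over the list alone (median 1.67, adjusted p = 1.3e-11), with the vesicle gene Rab3c up by 4.86 ± 0.11. All measured GABAergic genes rose (16 of 16, adjusted p = 3.9e-08), with Gad1 at 4.03 ± 0.10. Pan-neuronal genes (24 of 25 rose, adjusted p = 4.4e-14; adjusted p = 0.0535 with an estimated correlation) and proneural factors (17 rose, 4 fell, adjusted p = 5.9e-05; adjusted p = 0.0538 with an estimated correlation) rose, Neurod6 by 4.68 ± 0.07. Axon guidance genes (24 of 28, adjusted p = 1.5e-07), with the adhesion gene Chl1 at 5.44 ± 0.10, and the glutamate, acetylcholine and monoamine list (12 of 19, adjusted p = 0.00153), with Gria2 at 4.78 ± 0.16, rose as well. Glial genes rose (13 of 19, adjusted p = 1.5e-04), whereas the progenitor list was not called (adjusted p = 0.389), with Fabp7 of radial glia at 2.83 ± 0.15.

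Cell cycle lists fell almost entirely: 36 of 37 replication genes (adjusted p = 2.0e-15), with Cdc6 at -3.09 ± 0.13, and 32 of 34 mitotic genes (adjusted p = 3.9e-14), with the kinesin Kif20a at -2.08 ± 0.12. Ribosome biogenesis genes fell (35 of 36, median -1.24, adjusted p = 2.6e-15), with the polymerase I gene Polr1e at -2.55 ± 0.13. Brain patterning genes fell (16 of 25, adjusted p = 3.2e-04), with Six6 at -2.78 ± 0.15. Marker lists of other tissues also differed: macrophage genes rose (18 of 22, adjusted p = 3.9e-08, Csf1r by 3.83 ± 0.14), connective tissue genes rose (19 of 19, adjusted p = 5.2e-14), and skeletal muscle genes rose (20 of 22, adjusted p = 2.3e-11). Poly-A spike-ins differed by -2.86 and 18S ribosomal RNA by 3.49 between these stages.

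Further lists rose between E9.5 and E13.5. Cell cycle exit genes (14 of 15 rose, adjusted p = 7.7e-06), cartilage and bone genes (15 of 18, adjusted p = 3.8e-06) and lens and pigment genes (15 of 21, adjusted p = 2.3e-05) were higher. HOX genes rose (adjusted p = 0.00215; adjusted p = 0.132 with an estimated correlation), as did choroid plexus genes (adjusted p = 0.0151; adjusted p = 0.0807 with an estimated correlation). Oxidative phosphorylation subunits rose (adjusted p = 5.8e-06; adjusted p = 0.092 with an estimated correlation), and so did immediate early genes (adjusted p = 0.029; adjusted p = 0.0904 with an estimated correlation).

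Pluripotency-associated genes (10 of 16 fell, adjusted p = 4.6e-05), chaperones (27 of 33, adjusted p = 9.2e-08) and translation factors (17 of 29, adjusted p = 0.00576) fell. Erythroid genes fell (adjusted p = 0.00217; adjusted p = 0.255 with an estimated correlation), and spliceosome genes fell (adjusted p = 0.00606; adjusted p = 0.127 with an estimated correlation). Proteasome subunits (adjusted p = 0.0104; adjusted p = 0.127 with an estimated correlation), glycolysis genes (adjusted p = 0.0357; adjusted p = 0.39 with an estimated correlation) and tricarboxylic acid cycle genes (adjusted p = 0.0361; adjusted p = 0.126 with an estimated correlation) fell too. These last 3 calls were also lost with other settings: the second-brightest probe set for the proteasome (0.176) and the tricarboxylic acid cycle (0.0720), and the filter on dim genes for the latter and for glycolysis (0.0514). Glycolysis was not called without probe sets marked as shared either (0.0674). Not called were the neural crest (adjusted p = 0.155), endothelial (0.104), surface ectoderm (0.572), ribosomal protein (0.951), cholesterol (0.278), hypoxia (0.714), imprinted (0.0721) and histone lists (0.572). For ribosomal proteins and hypoxia the median and test were below 0 and the mean above.

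The intervals were set against each other gene by gene. Genes higher in both numbered 1408 (independent lists 1571), lower in both 1035 (1318), first higher then lower 2441 (1519) and first lower then higher 2009 (1363). Genes at least 2-fold changed in both numbered 176, 41, 175 and 86 in these classes, against 64.0, 33.2, 42.1 and 50.4 for independent lists. Both intervals share the 4 E11.5 arrays, and simulations of unchanged genes with these shared arrays gave 0 genes in each class. For genes without change the adjusted threshold all but fixes that outcome. It cannot show how the shared arrays act on the classes of changed genes. With the E11.5 arrays split between the intervals, the 4 classes held 1106 to 1308, 715 to 1002, 1673 to 1824 and 1467 to 1586 genes. Those at least 2-fold changed in both then numbered 173 to 210, 24 to 65, 161 to 178 and 82 to 94. Counts for independent lists were not recomputed for these split fits. The correlation of the changes across genes, which are not independent replicates, was -0.131, and between -0.146 and -0.0499 with the arrays split. Simulated unchanged genes, which vary by noise alone, gave -0.599. The covariance was -0.0546 (simulated -0.00803; between -0.06 and -0.0223 with the arrays split).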

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

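The tests of the 3 patterns weighed here were chosen only after the results were seen, and the splits of the arrays before. Samples far from the others of their stage were looked for with Dixon's ratio, the gap to the nearest sample over the whole range of the stage, at its 95% limit. The ratio was above its limit in 12 of 198 gene levels, 3 of 114 list medians and 2 of 30 control levels, where chance gives about 1 in 20.

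At E9.5, sample 24 was lowest for Nfia (ratio 0.667) and highest for Hspa9 (0.712) and Polr1e (0.846), and sample 16 was highest for the Gapdh 3′ minus 5′ difference (0.823). At E11.5, sample 33 was highest for Cnmd (ratio 1), Neurod6 (1) and C1qa (0.861), and sample 51 was highest for Hoxb5 (1) and for the 5′ beta-actin control (0.901) and lowest for Snap25 (0.890). The ratios of 1 lie at the dim end, where whole-number values put the other samples at 1 equal value. Sample 36 was lowest for the median of GABAergic lineage genes (0.866). At E13.5, sample B63E5K was lowest for Tnnt1 (0.650) and Sall4 (0.667), sample B62E7K was highest for Ndufs8 (0.782) and lowest for Chl1 (0.635) and for the mitotic list (0.643), and sample B62E8K was highest for the connective tissue list (0.636).

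The drawn splits argue against a chance division of the arrays as the source of the numbers of genes called. They cannot tell stage from the labelling kit or anything else that changed with stage. Among 100 drawn splits of the arrays of E9.5 and E11.5, the real split called 10520 genes and was the 1 split with as many; the highest other called 5418. For E11.5 and E13.5 the real split called 9981 genes, again the 1 split with as many, and the highest other 3796. For E9.5 and E13.5 the values were 11247, 1 split and 6442.

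A set of 23 probe sets was at least 3 log2 units higher at E11.5 than at both other stages, among them those of Depp1, Pik3cd, Sema3f, Nrip2, Kalrn and Laptm5. If all transcripts of these genes had risen, their other probe sets would rise too, yet in 17 genes with another probe set these rose by a median of 0.0955 (interquartile range -0.27 to 0.33), against 1.10 (0.65 to 2.28) in 21 genes whose probe set rose as much and stayed high (permutation p = 0.00018). Carried-over ribosomal RNA stays open: the 18S probe sets rose by 2.94 between E9.5 and E11.5, as these probe sets did, and by 0.55 between E11.5 and E13.5, when these fell, but the labelling kit changed with that step, so it cannot be told apart. A transcript form detected by a single probe set, or unspecific hybridisation on the E11.5 arrays, may remain as explanations, and neither was tested.

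Ribosome biogenesis genes fell by a median of 1.23 from E9.5 to E11.5. A shift shared by genes of the same brightness is argued against by 10000 random lists of matched brightness, of which 0 had a median as low (lowest -0.46). The DNA replication and mitotic lists fell less. Their lower quartiles (-0.90 and -0.65) lay above the ribosome biogenesis upper quartile of -1.004. A smaller share of neuroepithelial progenitors need not lower these lists equally, so the quartiles cannot decide whether it was the whole cause. The progenitor median was 0.63 (interquartile range 0.18 to 1.14, camera adjusted p = 0.236 with an estimated correlation). It cannot decide this either, since levels within progenitors can rise while their share falls. As the whole or a part of the fall, a smaller progenitor share stays open, as does a change within the progenitors. Of the genes concerned, 32 of 37 replication and 23 of 34 mitotic genes fell and 12 of 15 cell cycle exit genes rose. The poly-A spike-ins differed by -2.60 in the same interval. This exceeded the bound of 0.5 set for the test of a different amount of sample RNA per spike-in. Acting on all transcripts alike, such a difference would not move the list relative to the other transcripts. Whether it acted alike was not tested, so a different amount of sample RNA cannot be told apart from stage. A difference in handling that acted unevenly on transcripts cannot be told apart from stage. A change of growth with embryonic stage stays among the open explanations, untested.

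Muscle, cartilage and connective tissue genes rose from E11.5 to E13.5 by medians of 3.74, 1.66 and 1.68. Random lists of matched brightness gave 0 of 10000 medians as high for each list, which argues against a shift shared by genes of the same brightness. A lower share of neural tissue would raise markers of the tissues around it. The upper quartiles of 4 of 5 other non-neural lists lay below the muscle list's lower quartile of 1.11, the lens list being the exception. They were 0.034 for neural crest, 0.97 for endothelial, 0.91 for macrophage and 0.94 for surface ectoderm genes. The macrophage and surface ectoderm calls were lost with an estimated correlation (camera adjusted p = 0.0851 and 0.198). Such a share need not raise these lists equally, since vessels and microglia also lie within the brain and levels within cells can change. The quartiles therefore cannot decide whether it was the whole cause of the muscle rise. For connective tissue and cartilage 2 and 1 of the 5 lists lay apart in this way. A lower neural share stays open for muscle, connective tissue and cartilage genes. The progenitor median (-0.56, adjusted p = 0.468 with an estimated correlation) went with a lower neural share. The pan-neuronal median (0.92, adjusted p = 0.276 with an estimated correlation) and the synaptic median (0.75) went against it. The erythroid fall (median -0.77, adjusted p = 0.126 with an estimated correlation) may be a change within erythroid cells. An effect of the labelling kit cannot be told apart from stage, since 0 stages were measured with more than 1 kit, and growth of these tissues or a different extent of dissection may contribute, neither of which was tested.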

How the results depend on the processing

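The second-brightest probe set and leaving out the E9.5 samples 13 and 15 together were tests chosen after the results were seen. Of 111 gene results, 97 kept their side of the threshold, and their direction if called in the main fit, under every alternative run for them. Of 114 list results 52 did, counting camera with an estimated correlation and fry. For results not called in the main fit, direction was not compared. Leaving out 1 array at a time gave 5323 to 5685 genes higher and 4616 to 4903 lower in E11.5 versus E9.5, 4833 to 5183 and 4660 to 5037 in E13.5 versus E11.5, and 5710 to 6025 and 5064 to 5383 in E13.5 versus E9.5. Without the E9.5 samples 13 and 15 the counts were 5808 and 4896, 5361 and 5196, and 6077 and 5166. Quantile normalization and median centring moved the median of all genes by at most 0.00137 log2 units. The deposited values were already normalized between arrays, so these settings could change little and are a weak check. Testing all probe sets without choosing 1 per gene, which tests more features, gave 11703 higher and 11895 lower (2090 and 2143 at least 2-fold) in E11.5 versus E9.5, 11270 and 11917 (2456 and 2089) in E13.5 versus E11.5, and 12501 and 13462 (3531 and 3601) in E13.5 versus E9.5, with 32473 by the F test and 2474, 2516, 5432 and 4516 in the classes higher then higher, lower then lower, higher then lower and lower then higher. The mean of all probe sets of a gene gave 603 genes at least 2-fold higher in E11.5 versus E9.5, and 692 higher and 438 lower in E13.5 versus E11.5; the second-brightest probe set gave 715 at least 2-fold higher in E11.5 versus E9.5; the cause was not tested. With an estimated correlation, 8 of 11 lists were still called up and 9 of 13 down in E11.5 versus E9.5, 8 of 16 up and 1 of 8 down in E13.5 versus E11.5, and 11 of 17 up and 7 of 12 down in E13.5 versus E9.5. Fry, which does not compare lists with other genes, had 18 up in E11.5 versus E9.5 and 26 up in E13.5 versus E11.5. With the E11.5 arrays split, the correlation of the intervals was at its weakest -0.0499 and -0.0524.

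Some genes depended on the probe set. In E11.5 versus E9.5, Fen1 was called in the opposite direction at -0.85 both without probe sets marked as shared and with the second-brightest one. In E13.5 versus E11.5, the second-brightest probe sets of Depp1 (0.44) and Snap25 (-0.39) were called in the opposite direction. Those of Pik3cd (0.090) and Aldoc (-0.0085), and Kalrn under both settings (0.071), were near 0 and not called. The calls of Depp1, Pik3cd, Laptm5 and Nop10 in E11.5 versus E9.5 and of Nrip2, Gria2, Sox1 and Hbb-b2 in E13.5 versus E11.5 were lost with the second-brightest probe set. The fit with the title prefix as a random block gave no list tests, the fits of only the stages compared gave no F test, classes or list tests, and all probe sets gave counts only. No paired analysis was possible because the stages share no replicate numbers. Near the floor, at intensities of 4 or 5, differences are compressed, which limits changes of dim genes.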

Other observations

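No test was added after the result was seen for the values given here. Xist, which is expressed from an inactive X chromosome, was at log2 intensities of 9.69 to 10.03 on the 3 E9.5 arrays without Kdm5d signal, and at 12.13 to 12.60 and 12.69 to 12.85 on those of E11.5 and E13.5. On the arrays with Kdm5d signal it was at 4.39 to 4.81 at E9.5, 6.15 to 7.59 at E11.5 and 5.43 to 6.70 at E13.5. The highest of these, 7.59, was E11.5 sample 33, whose Kdm5d was at 7.17.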
